A study of Mus musculus with 9 samples.

How the data were processed

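Polyadenylated RNA of primary mouse cortical neurons was sequenced in 9 libraries, 3 each of normoxia, hypoxia and hypoxia with T3. The deposited table holds 1 column per library and 24054 rows of gene symbols, and its values are a signal that the authors scaled, TMM-normalized CPM. Per the submitters' processing notes, Bowtie2 2.1.0, RSEM 1.2.15, edgeR (version not given) and the mm10 genome were used; the annotation release and filters were not stated. The columns sum to 945822 to 1091200, so the values are not plain CPM. Within each column the values are whole multiples of a common step, the value of 1 read, in 99.84% to 99.99% of cells (within 0.01 reads), and from these steps the reads per library were recovered, 17182339 to 33937842 reads. Recovered reads are not molecules, and this depth measures counting error only.

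The libraries were grouped by their column headers and labels. The column numbers of the hypoxia and T3 libraries match no replicate number of the sample titles, so libraries were not paired and no replicate block was fitted. On the second principal component normoxia 1, hypoxia 7 and T3 11 stood at 14.3, 11.8 and 10.8 and the others at 4.4 or below; column order was not used to pair libraries. An unnamed column with 4 numbers was looked at and used in no test. Symbols were used as deposited; 27 had become dates, and 2 occurred more than once.

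Genes with more than 1 CPM in at least 3 libraries were kept (12923). All 9 libraries were fitted together in R 4.3.3 with limma 3.58.1 (lmFit, eBayes with a trend, 6 residual degrees of freedom) on log2 of the value plus 1. The tests were two-sided, with Benjamini-Hochberg adjustment over the 12923 genes and a threshold of 0.05. A log2 change is the difference of group means on that scale, with the SE of the fit; means and SDs are of the values themselves, n = 3. The 3 comparisons are hypoxia against normoxia, hypoxia with T3 against hypoxia, and hypoxia with T3 against normoxia.

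The groups, tests, 27 gene lists and the rule for named genes were set before the data were examined. The lists cover hypoxia, metabolism, thyroid hormone, chromatin, stress, neuron types, other cell types and RNA quality. Of them 25 had at least 3 members past the filter; the microglia list and the mitochondrially encoded transcripts did not and were not tested. Members were counted with adjustment over all genes and over the list alone. Lists were tested by camera with an inter-gene correlation of 0.01, adjusted over the lists; camera with an estimated correlation and fry were alternatives. With the estimated correlation the HIF-responsive list in hypoxia kept its call and no other call held.

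The named genes are, for each of hypoxia against normoxia and hypoxia with T3 against hypoxia, the 8 with the largest increase and the 8 with the largest decrease among those past the threshold with a mean of at least 5 CPM in the higher group and no overlap between the groups, leaving out predicted genes; up to 4 members of each list with the smallest adjusted p; and, as checks of the labels, Vegfa, Slc2a1, Pdk1, Bnip3, Adm, Egln3, Hr, Klf9, Dio3, Thrb and Dbp. Dio3 did not pass the filter on low values and has no test. The text names all of the first and the last kind and some of the list members; some others are not reported here. Fos, Egr1 and Rasd2 with T3, Plxnd1, Chgb, Hdac11 with T3, Bdnf, Kmt2a, Kmt2c, Kmt2d and Kdm5b fall outside it or are named for another reason and were chosen after their values were seen, as were the genes given for T3 against normoxia.

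The method was tested on simulated counts, drawn anew from the mean and spread of each gene in the recovered reads. Known changes were placed in a small part of the genes, upward and downward. For hypoxia with normoxia the method recovered 53.7%, 88.1% and 100.0% of genes changed 1.5, 2 and 4-fold, with 5.3% false calls. For T3 with hypoxia it recovered 71.6%, 88.1% and 100.0%, with 8.0% false calls. These rates need not hold in the real data, where 33.6% and 6.5% of the tested genes changed. Camera called the 1 shifted list and 0 of 20 unshifted ones. Draws made from the mean and spread of each gene carry no correlation between genes. In the data the estimated correlation ranged from -0.012 in the DNA methylation list to 0.778 in the neural progenitor and cell cycle list. The simulation therefore cannot tell how often camera with a preset correlation falsely calls lists whose genes vary together.

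The alternatives planned were another pseudocount (0.1 or 5), no filter or a mean of at least 5 CPM, only the 2 groups compared, median-of-ratios, equal-column-sum and quantile scaling, no variance trend, library weights, a threshold of 0.01, a 2-fold minimum, edgeR 4.0.16 quasi-likelihood and DESeq2 1.42.0 on recovered reads (on-step rows), and leaving out each library. Alternatives added after seeing the data were leaving out the 35 rows with values off the read step, setting those values to missing, setting the 36 that lie a whole number from whole reads to those reads, leaving out Rn45s and Lars2 with rescaling, and equal-column-sum scaling for the joint reading of both comparisons. A shift of values off the step by whole numbers was tried up to 30 with a tolerance of 2e-05 reads and 19 random draws; wider tolerances and ranges were tried first and gave more matches at random. A second common step was also searched, from 0.5 to 2 times the step of the library and within 0.01 reads, in the 6 libraries with at least 8 such values. Each group pair was also split in the 10 ways possible. Gene spans and coordinates came from GENCODE M21 and were matched by symbol for 12298 genes (95.2%). Figures and tables were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.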

Results

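Primary cortical neurons from C57BL/6 mice were kept in culture for 6 days, and their polyadenylated RNA was sequenced in 9 libraries. The libraries fell into 3 groups of 3: neurons in normal oxygen (normoxia), neurons in 0.2% oxygen for 7 hours (hypoxia), and neurons in the same low oxygen with 10 nM of the thyroid hormone triiodothyronine (hypoxia with T3). Libraries are named here by group and by the number in their column header, which runs 1 to 3 in normoxia, 7 to 9 in hypoxia and 11 to 13 in hypoxia with T3. Each value is a TMM-normalized CPM, a read count of a gene scaled by the size of its library, as made by the authors. The depth recovered from the values ranged from 17182339 reads in hypoxia 7 to 33937842 reads in normoxia 2. At these depths 1 read equalled 0.0302 to 0.0565 CPM. After a filter on low values 12923 genes were tested. The labels do not say whether the 3 libraries of a group came from separate cultures. The p-values of genes below weigh differences against the spread between these libraries, which may be technical. Those of gene lists build on the same spread, while Fisher's exact test below counts rows.

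In all but 35 rows of the table, every value was a whole number of reads of its library within 0.01 reads. The 35 other rows held 142 values that were not, of which 6 were in normoxia, 65 in hypoxia and 71 in hypoxia with T3. Of the 91 tested rows of histone-modifying enzymes, 20 were among the 35, against 0.12% of the other tested rows (Fisher's exact test, two-sided, p = 2.9e-35). Genes in these rows, which include Hr, Klf9, Vegfa, Dot1l, Hdac11 and Kmt2e, are given below with their values as deposited, and the main counts of genes and of list members that include them are given with and without them.

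The comparison of hypoxia with normoxia asked how cortical neurons respond to low oxygen. In hypoxic neurons 31 of 36 genes that respond to the hypoxia-inducible factors (HIF), 17 of 21 glycolysis genes and 23 of 30 immediate early genes were higher, and 18 of 37 glutamatergic neuron and synapse genes were lower (11 with equal column sums). With an estimated correlation between genes the HIF-responsive list passed (adjusted p = 0.044), and the other 3 did not (adjusted p = 0.066, 0.14 and 0.41). Slc2a1, the glucose transporter GLUT1, rose from 9.70 ± 0.422 to 55.7 ± 6.81 CPM (SD, n = 3), a log2 change of 2.40 (SE 0.10, adjusted p = 1.7e-07). Hk2, the hexokinase that starts glycolysis in many growing cells, rose from 1.77 ± 0.417 to 66.5 ± 22.1 CPM, a log2 change of 4.56 (SE 0.21, adjusted p = 2.1e-07). P4ha1, which hydroxylates collagen, rose by 2.06 on the log2 scale (SE 0.06, adjusted p = 7.1e-09). Among the falling genes were Grm8, a metabotropic glutamate receptor, with a log2 change of -1.83, Cadps2, which primes secretory vesicles, with -1.74, the large adhesion gene Csmd3, with -1.69, and the receptor phosphatase gene Ptprk, with -1.58.

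By limma, 4343 genes changed at an adjusted p under 0.05, of which 1846 were higher and 2497 lower in hypoxia. Of these, 221 changed at least 2-fold, 107 of them upward and 114 downward. Leaving out the 35 rows gave 4330 genes, 1842 higher and 2488 lower, 214 of them changed at least 2-fold. The split between higher and lower depended on the scaling of the libraries. When the libraries were rescaled to equal column sums, the median of all genes moved to 0.130 on the log2 scale and 76.3% of the changed genes were higher, against 42.5% as deposited.

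The fixed list of HIF-responsive genes, the targets of the hypoxia-inducible factors, had 31 of its 36 tested members higher and none lower (30 of 35 without the rows off the read step). Adjusted over the list alone, the count was also 31, and the list moved upward by camera with a preset correlation (adjusted p = 2.5e-24) and with an estimated correlation (adjusted p = 0.044). Members included Pdk1 (log2 change 1.78), a kinase that keeps pyruvate out of mitochondria, the mitophagy receptor Bnip3 (1.66), the oxygen sensor Egln3 (1.77) and the vasodilator peptide Adm (1.10). Vegfa, whose 3 values in hypoxia and 3 with T3 are off the read step, stood as deposited at 43.6 CPM in normoxia and 174 CPM in hypoxia (log2 change 1.98), and Gadd45g, a growth arrest gene with 1 such value, at 4.01 and 19.4 CPM (log2 change 2.04). In the glycolysis list 17 of 21 members were higher and none lower, also 17 adjusted over the list alone, with Pfkfb3 at 1.74 and Eno1 at 1.48. Its camera call (adjusted p = 1.9e-16) was lost with an estimated correlation (adjusted p = 0.066).

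Immediate early genes, which neurons switch on within minutes of stimulation, had 23 of 30 members higher and 2 lower (23 and 3 adjusted over the list alone, 22 and 1 of 28 without the rows off the read step). Egr1 rose by 2.52, Fos by 2.30, Arc by 1.92 and Jun by 1.36 on the log2 scale. The list's camera adjusted p was 4.9e-10, and the adjusted p was 0.14 with an estimated correlation. Of the unfolded protein and integrated stress response list 15 of 31 members were higher and 2 lower (16 and 2 adjusted over the list alone), among them the stress effectors Atf4 (0.76) and Ppp1r15a (1.28), with a camera adjusted p of 4.3e-05 and an adjusted p of 0.066 with an estimated correlation. Cytosolic ribosomal protein genes shifted upward by small amounts. Of 68 members 52 were higher, 60 adjusted over the list alone, with Rpl35 at 0.43 and a list median of 0.28; the camera adjusted p was 1.9e-16, and the adjusted p was 0.41 with an estimated correlation.

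The list of glutamatergic neuron and synapse genes had 18 of 37 members lower and 1 higher (20 and 1 adjusted over the list alone), but 11 lower and 7 higher when the libraries were rescaled to equal column sums. Gria2, a subunit of the AMPA receptor, fell by 0.75 and the layer 4 transcription factor Rorb fell by 1.10 on the log2 scale. The camera adjusted p was 0.00018, and the adjusted p was 0.41 with an estimated correlation. Of the GABAergic neuron list 2 of 21 members were lower and 1 higher, the same counts adjusted over the list alone, and the calcium-binding protein gene Calb1 fell by 1.29; the camera adjusted p was 0.81 and the list's median of 0.06 and its fry direction, downward, differed in sign. Ntrk2, the receptor for BDNF, fell by 0.97. Cholesterol biosynthesis genes had 9 of 23 members lower and none higher (11 lower and 1 higher adjusted over the list alone), and 3 lower and 1 higher with equal column sums. The camera adjusted p was 0.0074, the adjusted p was 0.51 with an estimated correlation, and without hypoxia 9 the camera adjusted p was 0.075.

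Thrb, which encodes thyroid hormone receptor beta, fell in hypoxia from 28.0 ± 0.635 to 11.1 ± 2.12 CPM (log2 change -1.28, adjusted p = 0.00012). Of 19 tested genes of thyroid hormone transport, metabolism and receptors, 6 were lower and none higher (also 6 adjusted over the list alone, 5 of 18 without the rows off the read step), and 4 were lower and 3 higher with equal column sums. The list's camera adjusted p was 0.13, and the adjusted p was 0.41 with an estimated correlation. Hr and Klf9, classical T3 targets, stood as deposited at log2 changes of 0.11 and 0.12, neither past the threshold (adjusted p = 0.47 and 0.49). Their values in hypoxia 9 lie 10 and 20 CPM below whole reads of that library, and with those whole reads in place the log2 changes were 0.57 and 0.40 (adjusted p = 0.2 and 0.24). Dbp, a clock gene that also answers T3, rose by 0.62 (adjusted p = 0.011).

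Transcripts tied to RNA handling and markers of other cells were also looked at. Rn45s, the 45S ribosomal RNA precursor, took 3.25% to 4.21% of the values in normoxia, 1.04% to 1.33% in hypoxia and 1.04% to 2.65% in hypoxia with T3. Its log2 change in hypoxia, as deposited, was -1.81 (adjusted p = 0.00084). After quantile normalization it was 0.00. That setting gives equal ranks the same value in every library, so it cannot test a row that ranks alike in all of them. Lars2 took 0.427% to 0.516% in normoxia and 0.091% to 0.332% in hypoxia, and Mir6236 fell by 1.79 on the log2 scale, as did Lars2. The astrocyte list had 3 of 16 members higher in hypoxia and none lower, also 3 adjusted over the list alone, with Ndrg2 at 0.90, Glul at 0.56 and Aldoc at 1.94. Its camera adjusted p was 0.0032, and the adjusted p was 0.44 with an estimated correlation. The mean of that list, relative to normoxia, was -0.01 in hypoxia 7, 0.97 in hypoxia 8 and 1.53 in hypoxia 9, and spanned -0.72 to 0.63 within normoxia. The call on Aldoc was lost without normoxia 1 (adjusted p = 0.097), hypoxia 8 (0.086) or hypoxia 9 (0.12). Large fold changes were also seen in the paralogs Eif3j2 (log2 change 5.66) and Eif3j1 (-4.44), between which reads can be divided; the call on Eif3j1 was lost without normoxia 1 (adjusted p = 0.079), normoxia 2 (0.078), normoxia 3 (0.068), hypoxia 7 (0.1) or hypoxia 9 (0.12).

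**Figure D1:**
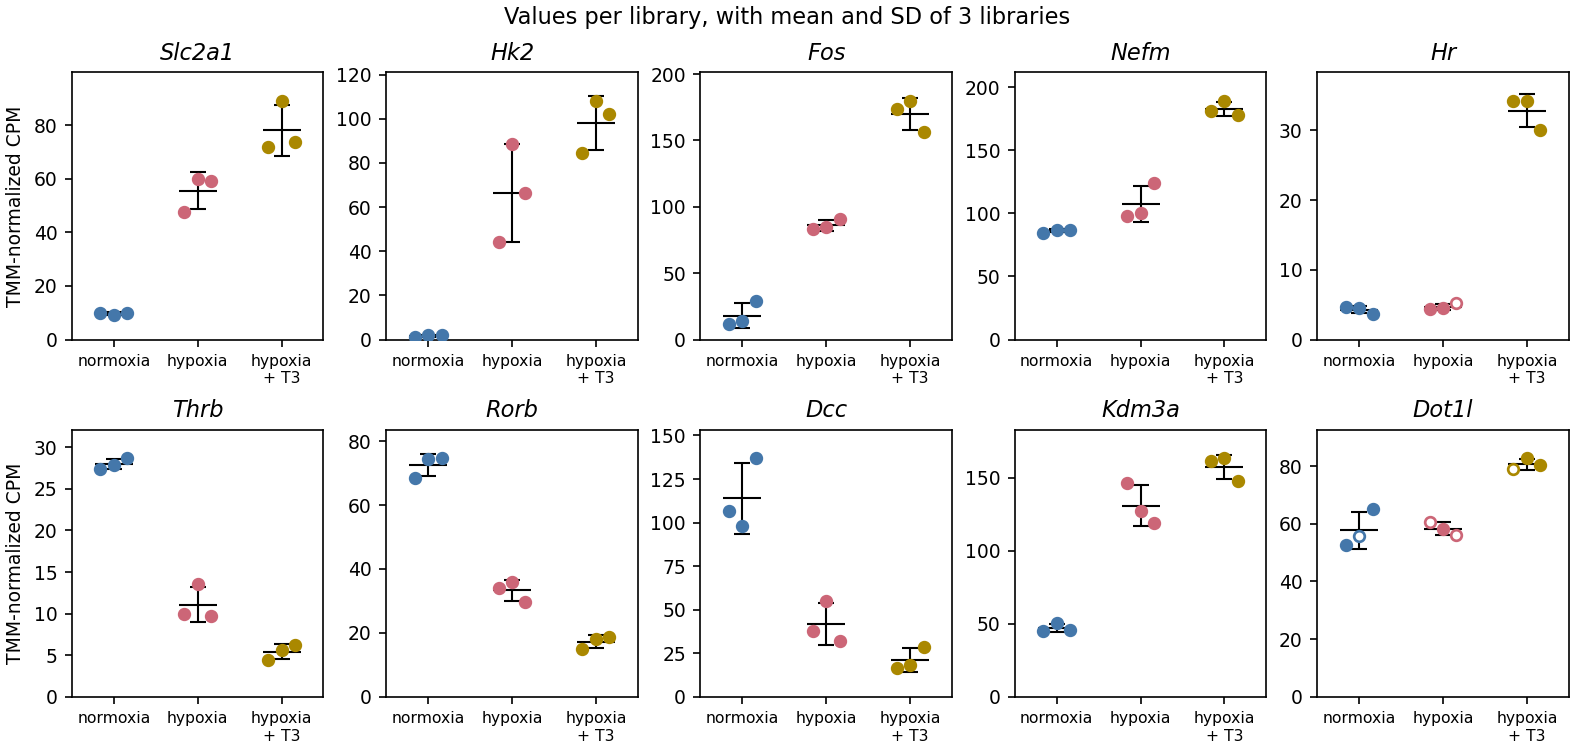
TMM-normalized CPM of 10 genes in each of the 9 libraries, with the mean and SD of 3 libraries per group as black bars; open points are values off the read step. Slc2a1, Hk2 and Fos were higher in every hypoxic library than in normoxia, Thrb and Rorb fell in hypoxia and again with T3, and Nefm averaged 107 CPM in hypoxia and 183 CPM with T3.

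The comparison of hypoxia with T3 against hypoxia asked what the hormone changed in hypoxic neurons. With the hormone 7 of 27 T3-responsive genes, 12 of 30 immediate early genes and 8 of 36 HIF-responsive genes were higher, and Unc5c, Dcc and Rorb, which hypoxia had lowered, were lower still. With an estimated correlation none of these 3 lists passed (adjusted p = 0.27, 0.29 and 0.27). By fry, which does not compare a list with other genes, they were upward (adjusted p = 0.0021, 0.017 and 0.017). Nefm, a neurofilament gene of the fixed T3-responsive list, rose from 107 ± 14.3 to 183 ± 5.82 CPM (log2 change 0.77, SE 0.08, adjusted p = 0.0018). As deposited, Hr, a corepressor that T3 induces directly, stood at 4.70 ± 0.435 and 32.9 ± 2.36 CPM (log2 change 2.57, adjusted p = 9.2e-07). Each of Hr, Klf9 (1.21, adjusted p = 0.0018) and the retinoic acid-degrading enzyme gene Cyp26b1 (1.44, adjusted p = 0.0009) had 1 value off the read step, in hypoxia 9, and with that value set to missing their log2 changes were 2.63, 1.31 and 1.55 (adjusted p = 7.6e-06, 0.0022 and 0.0022). These values lie 10, 20 and 20 CPM below whole reads of that library, and with the whole reads in place the log2 changes were 2.11, 0.94 and 1.21 (adjusted p = 0.014, 0.05 and 0.023), so the call on Klf9 was lost. The stress gene Gadd45b and the immediate early gene Junb, with 1 and 2 values off the step, stood at 1.95 and 1.13 as deposited and at 2.02 and 1.14 with these missing (adjusted p = 0.0022 and 0.02). The pro-apoptotic gene Bcl2l11 rose by 1.05, the small GTPase gene Arl4d by 1.04 and the cell cycle gene Sertad1 by 1.02.

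By limma, 838 genes changed, 353 higher and 485 lower with T3, and 17 of them changed at least 2-fold. The split was 284 higher and 697 lower with equal column sums, and turned to 143 and 132 with only these 6 libraries fitted and to 93 and 79 without the filter on low values. It was also 47 and 41 without hypoxia 7, 29 and 14 without hypoxia 8, 23 and 23 without hypoxia with T3 11, and 19 and 12 without hypoxia with T3 12. Leaving out the 35 rows gave 798 genes, 328 higher and 470 lower, 11 of them changed at least 2-fold. The count of 838 rested on single libraries: it was 88 without hypoxia 7, 43 without hypoxia 8, 46 without hypoxia with T3 11, 31 without hypoxia with T3 12, 1817 without hypoxia with T3 13 and 455 without normoxia 2. It was 172 without the filter on low values, 275 with only these 6 libraries fitted, 234 without a trend in the variance, 3050 with weights for each library and 1742 by DESeq2. The library hypoxia 9 stood nearer to the T3 libraries than the other hypoxia libraries did, at 14.0 on the first principal component against 2.9 and 2.5, with the T3 libraries at 17.6 to 32.0.

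Of the list of thyroid hormone-responsive genes of cortical neurons, 7 of 27 tested members were higher with T3 and 1 lower (4 and 1 of 24 without the rows off the read step), and 11 and 2 adjusted over the list alone. The list moved upward by camera (adjusted p = 0.00013), and the adjusted p was 0.27 with an estimated correlation. The mean of its 24 members on the read step, relative to normoxia, was 0.03 in hypoxia 7, 0.11 in hypoxia 8, 0.31 in hypoxia 9 and 0.37 to 0.38 in the T3 libraries. Rasd2, a striatal GTPase gene of the list, rose by 0.46. Dbp had a log2 change of 0.57 and did not pass (adjusted p = 0.052), but passed without normoxia 1 (0.047) or hypoxia 9 (0.04). Thrb fell again, from 11.1 ± 2.12 to 5.43 ± 0.927 CPM (log2 change -0.91, adjusted p = 0.011), a call lost without hypoxia with T3 12 (adjusted p = 0.052).

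Immediate early genes had 12 of 30 members higher with T3 and 1 lower (16 and 3 adjusted over the list alone, 11 and 1 of 28 without the rows off the read step), with Jun at 0.78, Ier2 at 0.83, Arc at 0.86, Fos at 0.97 and Egr1 at 0.78. The list's camera adjusted p was 1.1e-06, and the adjusted p was 0.29 with an estimated correlation. HIF-responsive genes had 8 of 36 members higher and none lower (12 adjusted over the list alone, 7 of 35 without the rows off the read step), with Pfkfb3 at 0.49, Stc2 at 0.76, P4ha1 at 0.35 and Slc2a1 at 0.48, while Pdk1 (0.08), Bnip3 (0.16), Adm (0.43) and Egln3 (0.17) did not pass. Vegfa stood at 0.44 as deposited, with all 6 of its values off the read step. The camera adjusted p was 5.4e-08, and the adjusted p was 0.27 with an estimated correlation. Ribosomal protein genes had 16 of 68 members higher, 65 adjusted over the list alone, and a median of 0.24; the camera adjusted p was 1.7e-25, and the adjusted p was 0.34 with an estimated correlation. Heat shock genes had 4 of 17 members higher (9 adjusted over the list alone), Hspa1b among them at 0.74; the camera adjusted p was 6.2e-06, and the adjusted p was 0.29 with an estimated correlation.

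Among the largest decreases with T3, Unc5c, a netrin receptor, fell by 1.24, its partner receptor Dcc fell by 0.95, the cadherin gene Cdh18 fell by 1.11 and the kinase gene Prkg1 fell by 0.95 on the log2 scale. Nwd2 fell by 1.05 and Nckap5 by 1.04. Rorb fell from 33.3 ± 3.23 to 17.2 ± 2.05 CPM (log2 change -0.91, adjusted p = 0.0018). In the glutamatergic list 7 of 37 members were lower and none higher (13 lower and 4 higher adjusted over the list alone), among them the synaptic adhesion gene Nlgn1 (-0.75). The list's camera adjusted p was 0.014, it was 0.11 without hypoxia 7 and 0.07 without hypoxia with T3 12, and the adjusted p was 0.76 with an estimated correlation. The GABAergic list held 2 lower members, Calb1 (-0.42) among them, and 1 higher, Calb2 (0.59), of 21 (the same counts adjusted over the list alone; camera adjusted p = 0.31, 0.0033 without hypoxia 8 and 0.0012 without hypoxia with T3 11; 0.96 with an estimated correlation).

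Of the 46 genes named for this comparison, 40 passed the threshold. The calls of 14 of the 40 held when any single library was left out. Those on the read step were Nefm, Jun, Ier2, Pfkfb3, Arl4d and Rorb. The rest of the 14, Hr, Klf9, Cyp26b1, Gadd45b, Junb, Hdac4, Kdm6b and Hdac9, are rows with values off the read step. Their leave-one-out fits used the values as deposited, and the call on Klf9 was lost with whole reads in place. The other 26 calls were lost without at least 1 library. The highest adjusted p came without hypoxia 8 for Dcc (0.14), Unc5c, Bcl2l11 and Kdm6a (0.12), Cdh18 and Vegfa (0.11), Sirt1 and Kmt2e (0.089), Calb1 (0.083), P4ha1 (0.072), Stc2, Sertad1 and Dot1l (0.068) and Fos (0.14). For Dcc, Unc5c, Bcl2l11, Kdm6a, Vegfa and Fos the rounded value was the same without hypoxia with T3 11. It came without hypoxia with T3 11 for Nckap5 (0.17), Jmjd6 (0.16), Egr1 (0.14), Nlgn1 (0.13), Rasd2 (0.12), Hspa1b (0.095) and Calb2 (0.087), and without hypoxia with T3 12 for Slc2a1 (0.11), Nwd2 (0.065), Prkg1 (0.064), Arc (0.063) and Thrb (0.052).

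**Figure D2:**
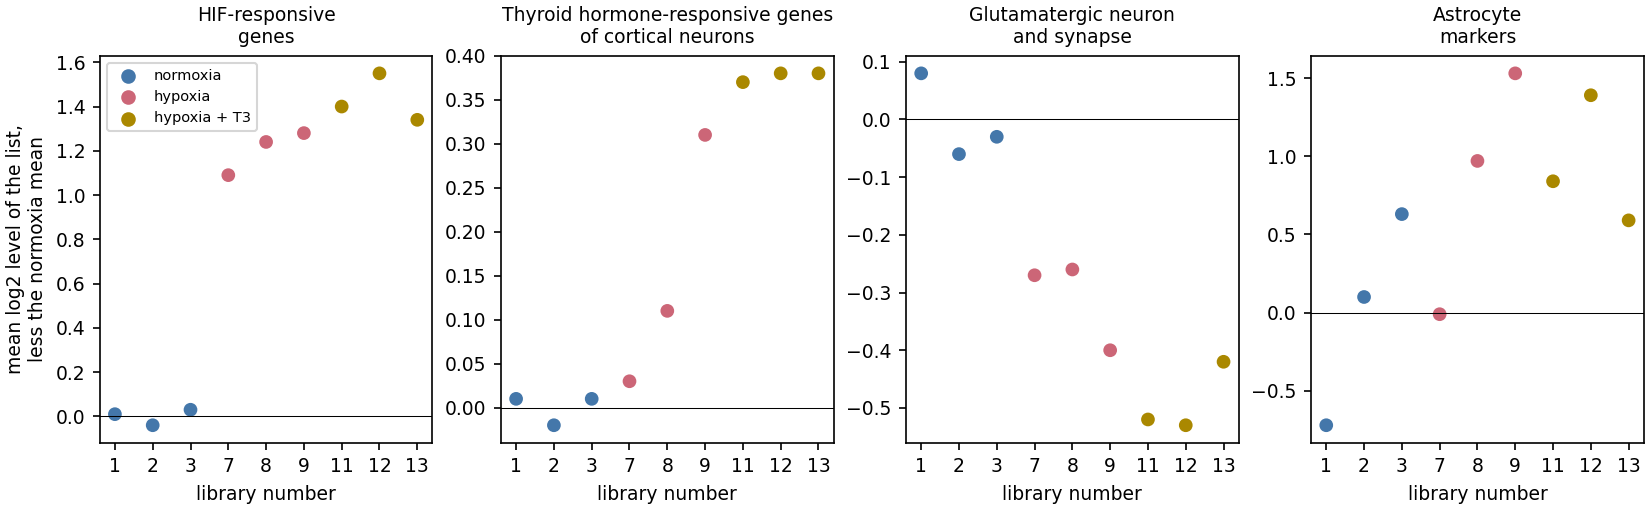
Mean log2 level of 4 fixed gene lists in each of the 9 libraries, less the normoxia mean, with library numbers on the horizontal axis and colours for the groups; rows off the read step are left out. The astrocyte list ranged from -0.72 to 1.53 and the T3-responsive list stood at 0.31 in hypoxia 9.

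Histone-modifying enzymes are of interest because the series title names thyroid hormone and histone modification. In hypoxia, the demethylase gene Kdm3a, a known HIF target, rose from 47.1 ± 2.98 to 131 ± 14.1 CPM (log2 change 1.45, adjusted p = 7.6e-07), Jmjd6 rose by 0.98 and Kdm2a by 0.37. The methyltransferase genes Smyd3 (-0.73) and Suv39h1 (-0.40) and the DNA methyltransferase gene Dnmt3a (-0.41) fell. Among the 22 tested demethylase rows on the read step 4 were higher and 5 lower in hypoxia, among 25 methyltransferase rows 1 was higher and 6 lower, and among 24 acetyltransferase, deacetylase and sirtuin rows 2 were higher and 5 lower. Counted with the rows off the read step, the methyltransferases had 3 higher and 9 lower (also 3 and 9 adjusted over the list alone), which became 8 higher and 6 lower with equal column sums, and the acetyltransferase list 3 and 9 (4 and 9 adjusted over the list alone), which became 8 and 4. With T3, of the same rows on the read step 1 demethylase was higher and 1 lower, 1 methyltransferase was lower and none higher, and none of the 24 others changed by limma. The 2 demethylases were Jmjd6 (0.33, adjusted p = 0.041) and Kdm6a (-0.59, adjusted p = 0.034), and both calls were lost without at least 1 library, at adjusted p up to 0.16 without hypoxia with T3 11 for Jmjd6 and 0.12 without hypoxia 8 for Kdm6a.

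The remaining histone-modifier calls with T3 were in rows with values off the read step. As deposited, Dot1l, which methylates histone H3 at lysine 79, stood at 58.3 ± 2.14 CPM in hypoxia and 80.7 ± 1.91 CPM with T3 (log2 change 0.46, adjusted p = 0.013), and with its 4 values off the step set to missing at 0.48 (adjusted p = 0.068). Kdm6b stood at 0.46 (adjusted p = 0.0065) and at 0.46 with such values missing (0.036), Hdac9 at -0.84 (0.002) and -1.01 (0.0069), and Sirt1 at 0.54 (0.019) and 0.60 (0.063). With whole reads in place of the values that lie a whole number from them, Sirt1 stood at 0.37 (0.064) and the other 3 calls held. The off-step values of Dot1l in hypoxia and some of Kdm6b with T3 were not among those replaced and stayed as deposited. All 3 values of Hdac4 with T3 (log2 change -1.06) were off the step, so no such change can be given without them. The hypoxic and T3 values of Hdac11 and Kmt2e had a relation of their own. Each of the 6 Hdac11 values was a whole number of reads of a library of the other group (hypoxia 7 with T3 11, 8 with 12 and 9 with 13), within 2.0e-05 reads. The same held for 2 of the 6 Kmt2e values, and the other 4 lay 10, 20, 20 and 20 CPM from such whole reads. As deposited the log2 change with T3 was -0.25 for Hdac11 and 0.25 for Kmt2e (adjusted p = 0.053 and 0.02), and exchanging the values of the 2 groups would turn both signs.

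**Figure D3:**
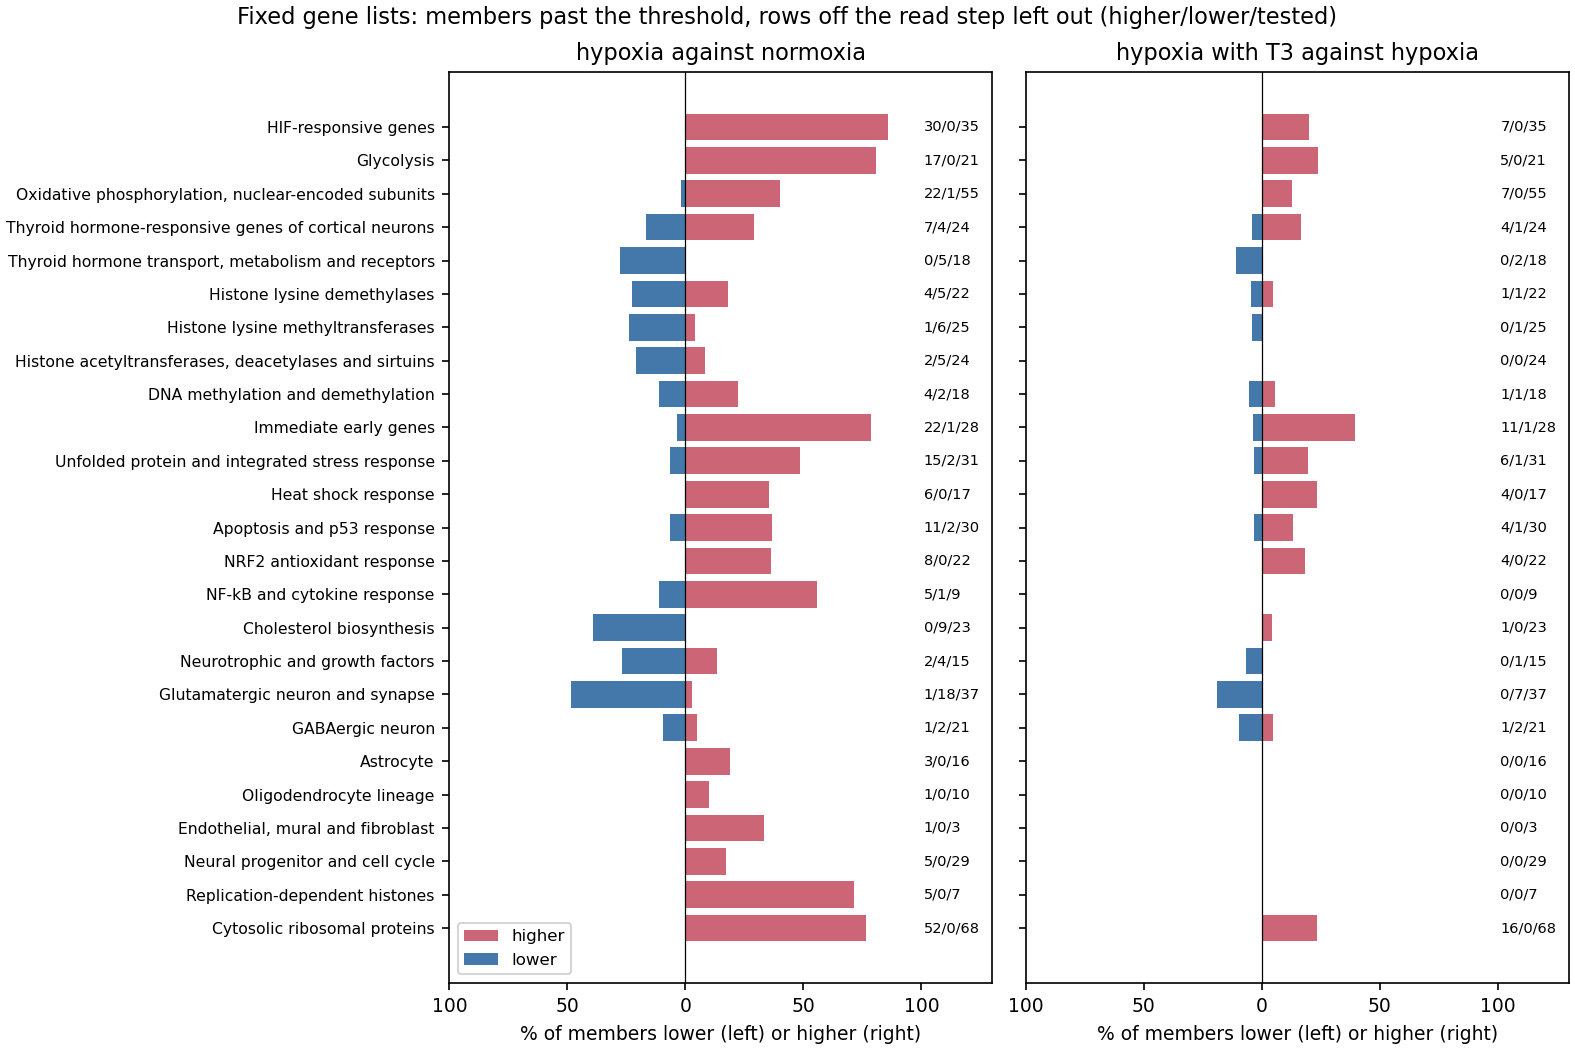
Percent of the tested members of 25 fixed gene lists that were higher (right) or lower (left) at an adjusted p under 0.05, in hypoxia against normoxia and in hypoxia with T3 against hypoxia, with the counts of higher, lower and tested members beside each bar; rows off the read step are left out. In hypoxia 30 of 35 HIF-responsive genes were higher, and 18 of 37 glutamatergic genes were lower on the deposited scale (11 with equal column sums).

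The comparison of hypoxia with T3 against normoxia, and the joint reading of the other comparisons, asked whether T3 moved the hypoxic neurons back toward normoxia. The changes with T3 mostly ran in the direction hypoxia had already taken: Fos, Egr1 and Arc rose further, and Thrb, Rorb and Dcc fell further. In the genome Fos, Egr1 and Arc span 3.4, 5.2 and 3.5 kb, and Thrb, Rorb and Dcc 377.8, 180.6 and 1097.4 kb. In hypoxia against normoxia and with T3 against hypoxia, log2 changes fell with gene span (Spearman's rho -0.47 in each). Against normoxia the T3 neurons showed Hk2 higher by 5.17, Slc2a1 by 2.88 and Nefm by 1.08 on the log2 scale, while Thrb fell by 2.19, Rorb fell by 2.02 and Dcc fell by 2.40. As deposited, Hr stood at 2.68 and Klf9 at 1.33. By limma 7117 genes changed in this comparison, 3300 higher and 3817 lower, 788 of them at least 2-fold; leaving out the 35 rows gave 7097, 3286 higher and 3811 lower, 777 at least 2-fold. More genes were higher than lower with equal column sums (4527 against 2856) and after quantile normalization (3794 against 3450), and fewer with median-of-ratios scaling (3444 against 3699).

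Of the 4343 genes changed by hypoxia, 581 also changed with T3, 559 in the same direction and 22 in the opposite direction. Independent lists of these sizes would share 144 and 137. In a new fit without the rows off the read step the same-direction count was 539 and the opposite count 13. In the main fit 18 of the 581 genes were such rows, 9 of them among the 22. The opposite count was 13, 9 and 14 without normoxia 1, 2 and 3, 3 without hypoxia 7, 1 without hypoxia 8, 0 without hypoxia with T3 11 or 12, 34 without hypoxia with T3 13, and 6 without the filter on low values. The same-direction count moved as far, to 297 without normoxia 2, 68 without hypoxia 7, 35 without hypoxia 8, 39 and 25 without hypoxia with T3 11 and 12, 1248 without hypoxia with T3 13, and 115 without the filter. Examples of the opposite direction on the read step, chosen after their values were seen, were Plxnd1 and Chgb. Plxnd1, a semaphorin receptor, stood at 682 CPM in normoxia, 514 in hypoxia and 614 with T3. The granin gene Chgb stood at 296, 263 and 329. Across genes, which are not independent replicates, the Pearson r of the hypoxia and the T3 log2 changes was 0.514, and 0.322 without hypoxia 7. In simulations without any effect r averaged -0.499, because both comparisons share the hypoxia libraries.

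**Figure D4:**
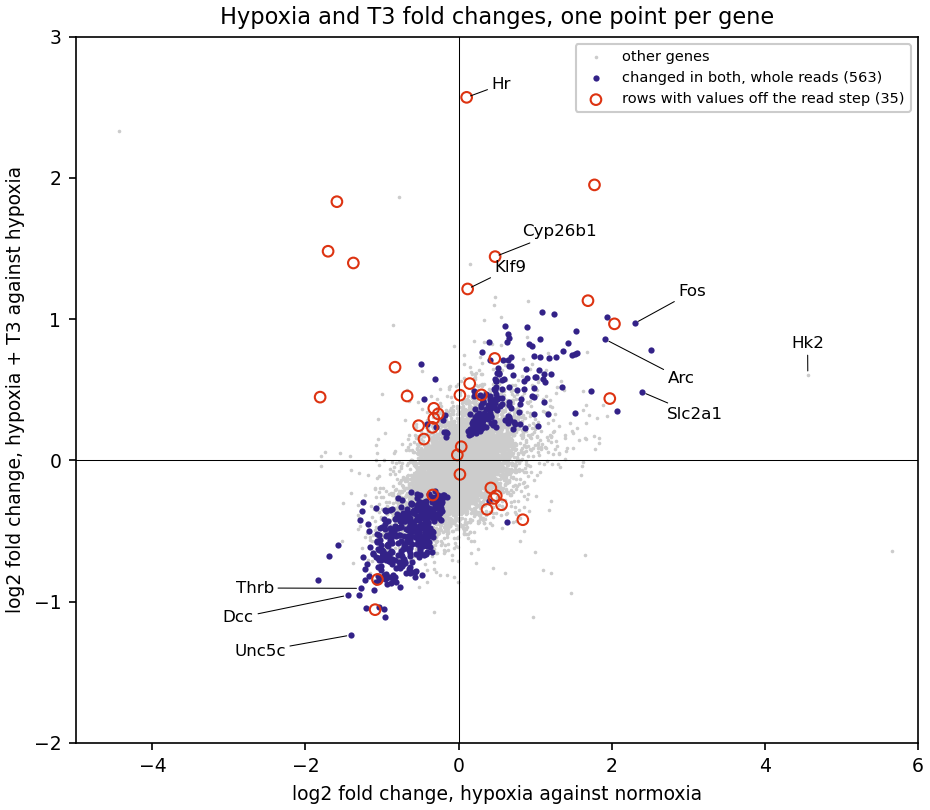
Log2 fold change in hypoxia against normoxia (horizontal) and with T3 against hypoxia (vertical) for the 12923 genes tested; dark points are 563 genes changed in both comparisons and on the read step, open circles the 35 rows with values off the step. Of the genes changed in both comparisons, 559 changed in the same direction and 22 in opposite directions.

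In the GRCm38 (mm10) assembly, Hr lies on chromosome 14 from 70552212 to 70573548, Thrb on chromosome 14 from 17660261 to 18038090, Slc2a1 on chromosome 4 from 119108711 to 119137983, Hk2 on chromosome 6 from 82725025 to 82774454, Nefm on chromosome 14 from 68082590 to 68124846, and Dcc on chromosome 18 from 71253634 to 72351069. All are protein-coding genes.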

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

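The relation of the values off the read step to whole reads, to other libraries and to the groups was tested only after those values had been seen; the splits of the libraries were planned.

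Numbers stand outside the 9 libraries' columns in an unnamed column, where no comparison uses them: 34.5 in the row of Bdnf, 58.3 in the row of Dot1l, 80.7 in the next row, Doxl2, and 1.38 in the row after it, Dpagt1. The values 58.3 and 80.7 equal the means of the hypoxia and of the T3 values of Dot1l, and 1.38 is their ratio. Groups of 3 libraries were not tested for outlying libraries.

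The 35 rows with values off the read step are the first pattern weighed. Against reads shared among paralogs and counted in fractions, 4.2% of the 142 values lie in normoxia (exact Clopper-Pearson upper limit 8.97%), where an even spread over the groups would be needed. That limit takes the values as independent, but many of them share a row, so it may be too low. Consistent with whole numbers added to or taken from values, 36 of 141 such values tried lie a whole number of at most 30 from whole reads of their own library, where the highest of 19 random draws gave 2; 23 of the 36 lie below the whole reads, among them Hr, Klf9 and Cyp26b1 in hypoxia 9, by 10, 20 and 20. In line with values exchanged between hypoxia and T3 libraries, 8 values of Hdac11 and Kmt2e are whole reads of a library of the other group (random highest 1); further, Kmt2a and Kmt2d hold equal values in 4 libraries, and Kdm5b, Kmt2a and Kmt2c are all at 5.57 in hypoxia 8. Neither relation holds for 97 of the 141 values; a search for a second step common to the values of a library found one for more values than any random draw in hypoxia 7 (11 of 21, random highest 6), 8 (9 of 18, 6) and 9 (10 of 25, 7) and T3 13 (8 of 27, 7) and not in T3 11 (7 of 22, 7) or 12 (6 of 22, 7); how any of them arose stays open, and no biological explanation was tested.

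With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. In each comparison 1 split, the real one, gave as many genes as the real one: it gave 4343 genes in hypoxia against normoxia (highest other 0), 838 with T3 against hypoxia (highest other 1) and 7117 with T3 against normoxia (highest other 0). Each other split mixes the groups compared, so their difference enters the spread. The few calls there therefore say nothing on chance.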

How the results depend on the processing

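Alternatives that leave out or replace rows or values off the read step, or leave out Rn45s and Lars2, and equal column sums for changes back by T3 and the correlation, were chosen only after the data were seen; all others were planned. Hypoxia against normoxia gave 4343 genes, 2959 to 4372 without single libraries, 2177 at a threshold of 0.01 and 221 with a 2-fold minimum. T3 against hypoxia gave 838 genes, 31 to 1817 without single libraries, 172 with no filter, 275 with only the 2 groups, 234 without a trend, 3050 with library weights, 36 at 0.01, 17 with a 2-fold minimum and 1742 by DESeq2. T3 against normoxia gave 7117 genes, 5957 to 7120 without single libraries and 788 with a 2-fold minimum. Changes back by T3 numbered 22, 0 to 34 without single libraries, 6 with no filter, 13 with off-step rows left out and 13 with off-step values missing. The correlation of fold changes was 0.514, 0.322 to 0.540 without single libraries and 0.440 with a pseudocount of 0.1. Lists past the threshold by camera numbered 17, 11 and 14, then 1, 0 and 0 with an estimated correlation, and 16, 9 and 20 by fry. Without single libraries the camera counts were 16 to 17, 9 to 12 and 13 to 15. The histone lysine demethylases with T3 against normoxia, downward by camera (adjusted p = 0.87), were upward by fry (0.0059). A stricter threshold or a fold minimum lowers counts by construction. Leaving out single libraries moved counts both ways, as the ranges above show. The cause of those and the other shifts was not tested. Of 1478 other settings of single named genes 1415 kept side and direction, 52 lost the call, 11 gained it and 0 reversed; of 918 leave-one-out values 809 kept it, 107 lost it and 2 gained it, with 99 of the 107 in T3 against hypoxia. No paired analysis was possible because the hypoxia and T3 column numbers match no replicate number of the titles, so the replicate block was not run; lists were not run under every setting. With 1 read at 0.0302 to 0.0565 CPM, genes under about 1 CPM in 7 or more libraries were not tested, and depth limits what can be said of them.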

Other observations

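The trend with gene length, the covariance, scaling and HIF tests of the direction of T3 changes, and the tests of hypoxia 9 were chosen only after the results were seen; the simulation behind the covariance and the gene lists were planned.

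Long genes were more often lower than higher in both comparisons. Of 1956 tested genes spanning at least 100 kb, 1083 (55.4%) were lower and 45 higher in hypoxia, with a median log2 change of -0.33; of 2898 genes under 10 kb, 192 were lower and 731 higher, with a median of 0.13. With T3 against hypoxia 294 (15%) of the long genes were lower and 8 higher (median -0.23), and 28 short genes were lower and 166 higher (median 0.08). Examples are Csmd3 with a span of 1211.4 kb, Dcc with 1097.4 kb and Thrb with 377.8 kb. The median of long genes, relative to normoxia, was -0.36, -0.27 and -0.38 in hypoxia 7, 8 and 9 and -0.66, -0.55 and -0.41 in T3 11, 12 and 13. Across 12298 genes Spearman's rho of the log2 change with span was -0.47 in both comparisons; with the longest mRNA's length it was -0.34 and -0.42, and with span at a given mRNA length -0.35 and -0.30.

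Further lists in hypoxia against normoxia, with higher, lower and tested members and the camera adjusted p, then that with an estimated correlation, were as follows. Oxidative phosphorylation had 22, 1 and 55 (3e-05, then 0.44), with Ndufa4 at 0.42, heat shock 6, 0 and 17 (0.0036, then 0.41), apoptosis and p53 13, 2 and 32 (11, 2 and 30 without rows off the read step; 0.00049, then 0.22), with Cdkn1a at 0.64, and NRF2 antioxidant genes 8, 0 and 22 (0.0023, then 0.41), with Hmox1 at 1.66. NF-kB genes had 5, 1 and 9 (0.021, then 0.29), replication-dependent histones 5, 0 and 7 (0.0036, then 0.41), with Hist1h1c at 0.81, and neural progenitor and cell cycle genes 5, 0 and 29 (0.00049, then 0.49). The NF-kB call was also lost with a filter of a mean of at least 5 CPM (0.35). DNA methylation genes had 6, 2 and 20 (0.04, then 0.22), with the call lost without rows off the read step (4, 2 and 18; 0.26), normoxia 2 (0.062), hypoxia 7 (0.066) or T3 13 (0.056). Oligodendrocyte genes had 1, 0 and 10 (0.027, then 0.43), with the call lost without normoxia 1 (0.12) or hypoxia 8 (0.1), endothelial, mural and fibroblast genes 1, 0 and 3 (0.24, then 0.44), neurotrophic factors 3, 5 and 17 (2, 4 and 15 without such rows; 0.45, then 0.5) and T3-responsive genes 8, 4 and 27 (7, 4 and 24; 0.13, then 0.41). The chromatin lists had camera adjusted p of 0.81 for demethylases (6, 5 and 26; 4, 5 and 22 without such rows), 0.2 for methyltransferases and 0.23 for acetyltransferases and deacetylases, then 0.87, 0.44 and 0.44.

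With T3 against hypoxia, glycolysis had 5, 0 and 21 (2e-08, then 0.27), oxidative phosphorylation 7, 0 and 55 (6.8e-16, then 0.34), the unfolded protein list 6, 1 and 31 (0.02, then 0.29; 0.075 without T3 13), NRF2 genes 4, 0 and 22 (0.00029, then 0.36) and cholesterol biosynthesis 1, 0 and 23 (0.0045, then 0.76). The cholesterol call was lost without hypoxia 9 (0.35), T3 11 (0.065) or T3 13 (0.056). Not past the threshold were apoptosis and p53 (4, 2 and 32, without rows off the step 4, 1 and 30; 0.22), NF-kB (0, 0 and 9; 0.68), neurotrophic factors (1, 1 and 17, without 0, 1 and 15; 0.22), thyroid hormone transport (0, 3 and 19, without 0, 2 and 18; 0.15), demethylases (3, 2 and 26, without 1, 1 and 22; 0.83), methyltransferases (4, 2 and 35, without 0, 1 and 25; 0.91), acetyltransferases and deacetylases (3, 2 and 30, without 0, 0 and 24; 0.99), DNA methylation (3, 1 and 20, without 1, 1 and 18; 0.93), astrocytes (0, 0 and 16; 0.44), oligodendrocytes (0, 0 and 10; 0.91), endothelial cells (0, 0 and 3; 0.91), progenitors (0, 0 and 29; 0.44) and histones (0, 0 and 7; 0.91). The astrocyte and progenitor lists passed without hypoxia 9 (0.021 and 0.041), and the GABAergic list without hypoxia 8 (0.0033) or T3 11 (0.0012).

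The second pattern weighed is that T3 changes run in the direction of the hypoxia changes. Against the shared hypoxia libraries as its source, the covariance of the log2 changes was 0.0422, where simulations without effects averaged -0.0082 and reached -0.0073. Against the scaling, at least 96.6% of the genes changed in both went the same way under median-of-ratios, equal-column-sum and quantile scaling, of which equal column sums moved the median of all genes most (0.130 in hypoxia and -0.038 with T3). A stronger hypoxia response in the dishes with T3 cannot be told apart from an effect of the hormone: the median of the HIF-responsive list was 0.20, which would be in line with it, but the adjusted p was 0.27 with an estimated correlation, and oxygen was not measured per dish. Both sets of changes also went with gene span (Spearman's rho -0.47 in each), and whether they share a direction at a given span was not tested. An action of T3 itself, which the design names, stays open and untested.

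The third pattern weighed is that the library labelled hypoxia 9 lies toward the T3 libraries at T3-responsive genes. On the 24 members on the read step it lay 0.78 of the way from the other hypoxia libraries to the T3 libraries. Hypoxia 8 lay at -0.28 and hypoxia 7 at -1.10, from baselines that included hypoxia 9 and so placed both lower. The list means, relative to normoxia, were 0.03, 0.11 and 0.31 in hypoxia 7, 8 and 9. On a hypoxia response further along, genes changed 2-fold by hypoxia lay 0.05 of the hypoxia change further along in hypoxia 9. In the same test hypoxia 7 and 8 lay at -0.18 and -0.21. The genes were chosen on the other hypoxia libraries, which were also the baseline. This can place a left-out library too low, so the test cannot decide. Against more astrocytes, the largest slope within a group gave a log2 shift of 0.09, against the list's excess of 0.24. The astrocyte list itself, however, was 1.05 higher in hypoxia 9 than in the other hypoxia libraries. Whether T3 was in that culture or library stays open: 393 genes outside the list, called with T3 and not called in hypoxia when hypoxia 9 was left out, lay in the median 0.46 of the way (quartiles 0.29 and 0.63), short of 0.5, and without hypoxia 7 or 8 that test held only 2 and 0 genes. These genes too were chosen on the other hypoxia libraries, which were the baseline. That can place a left-out library too near the T3 libraries, so this test cannot decide either. The whole reads above the deposited values of Hr, Klf9 and Cyp26b1 in hypoxia 9 (5.19, 24.8 and 30.3 CPM) stand at 15.2, 44.8 and 50.3 CPM, nearer to the T3 libraries (from 30.1, 48 and 65.3 CPM) than any other hypoxia library (up to 4.55, 20.4 and 29 CPM), and which values are right cannot be read from the table. Neither a mixed sample nor an exchange of samples can be settled from these values.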
